A study of Paenibacillus riograndensis SBR5 with 4 samples.

How the data were processed

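RNA of the nitrogen-fixing soil bacterium Paenibacillus riograndensis SBR5 was measured in 4 libraries from stationary cultures in KB medium. Of these, 2 were labelled sufficient iron and 2 limited iron. Per the labels' protocols, total RNA was extracted with TRIzol and treated with DNase, ribosomal RNA was removed with a bacterial mRNA enrichment kit, and cDNA libraries were made with a whole transcriptome kit followed by emulsion PCR. The iron concentrations, the sequencer, the read mapper, the counting rules and the genome assembly are not given in the sources used here.

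Each library came with a table of RPKM values (reads per kilobase of feature, scaled to the reads of the library) over 6093 features, per the file headers. Each library also came with a deposited list of distinct read sequences, with a whole-number count of reads for each. Of the features, 1345 carried a gene symbol, which gave 1107 distinct symbols, and 4748 carried only an identifier that the files do not pair with a name. Contig coordinates were given for 411 features whose symbol occurs more than once, and those coordinates are quoted as the deposited RPKM tables give them. No genome was used here, so the read sequences were not mapped, and features that overlap, that are fragments of a gene or that share reads with a near copy could not be told from others. Whether counting used strand is not given in the sources used here.

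The deposited RPKM values were whole multiples of the value of a single read. For features of known length, 100% of the values above 0 came out whole within a tolerance of 0.001 reads. The step size gave the number of reads assigned to features in each library, and the reads and length of every feature followed from the smallest common fraction of its 4 values. The recovered reads summed to between 99.95% and 100.17% of those totals. Lengths that became 3n + 1 when doubled were doubled, with their reads, except for first features of a contig. After this step, 99.2% of the recovered lengths were 3n + 1, as for coding lengths counted as end minus start. The doubling itself gives such lengths, so this share does not test the recovered lengths. On simulated data, the recovery returned the true reads for 99.7% of 1500 features. Their lengths were all drawn as 3n + 1, so the doubling was right there by design. Intervals on shares of reads are exact binomial 95% intervals, floors are 3 reads, and both cover counting error only, because PCR copies are not independent molecules.

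The main test was limma 3.58.1 with a mean-variance trend on log2(RPKM + 1), two-sided, over features with a mean RPKM of at least 5, with Benjamini-Hochberg adjustment and a threshold of 0.05. A difference on this scale understates the change of low features. Because RPKM is not a count, the count tests were alternatives: edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0, both on the recovered reads, in R 4.3.3. Differences of single genes and lists are given relative to the median of all tested features, as relative log2 differences with the limma standard error (SE). Gene lists were fixed before the data were examined and matched by whole symbol, because the files hold no product names. They were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists that had at least 5 tested members. The stable RNA list matched 0 features. Tables and plots were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

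The rule for named genes was also fixed before the data were examined. It took the 12 largest rises and the 12 largest falls with a symbol among those past the threshold and, where fewer passed, the smallest raw p in that direction, as values only. It added up to 4 members of each list with the smallest p, and fur, spo0A, sigE, sigF, sigG, sigK, nifH, abrB, sodA, katA and hag wherever a feature had that symbol. No feature was named hag. Features without a symbol were limited to 2 in each direction. Another 2 features with the symbol feoB were added after their values were seen.

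The limma, edgeR, DESeq2 and camera steps were tested on simulated data in which reads were drawn for the real features with the spread between these libraries. Of 100 features changed 4-fold and 100 changed 16-fold between simulated limited and sufficient iron, limma found 0 and 0 among 6079 features tested, and edgeR found 0 and 0 among 4619. DESeq2 found 23 and 92 and called 78 unchanged features among 6093. A list of 58 genes raised 2-fold in the simulated limited iron libraries passed the camera test among 6077 features. Simulated features were drawn independently, whereas the estimated correlation between members was 0.29 in the tested list of 58 sporulation genes. The simulation therefore does not show that a 2-fold shift of a real list would pass.

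The labels give each group the replicate numbers 1 and 2 and do not say that a number marks a shared day or that the samples of a group came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical. Alternatives were other pseudocounts and filters, other scalings, other limma settings, the replicate number as a block, the count tests, other set tests, removal of the 10 most abundant features, and each library left out in turn. In the read lists, reads were counted that hold the internal adaptor used in SOLiD barcoded libraries or the start of the P1 adaptor, and reads that hold conserved ribosomal RNA primer sites were counted among the remaining reads.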

Results

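Transcript levels of P. riograndensis SBR5 in stationary phase were compared between limited and sufficient iron, with 2 libraries in each group. Reads assigned to features numbered 311425 and 521788 in sufficient iron replicates 1 and 2, and 408985 and 298135 in limited iron replicates 1 and 2. The median feature held 15, 15, 25 and 12 reads, in the same order. Between 14.6% of features in limited iron replicate 1 and 38.9% in limited iron replicate 2 held fewer than 10 reads. For a feature of 1 kb, the floor of 3 reads lay between 5.75 and 10.1 RPKM.

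The libraries differed in make-up within each group. In sufficient iron replicate 2, the feature appA on contig 260 (4181 to 5649) alone held 198997 reads, 38.1% of those assigned (exact 95% interval 38.0 to 38.3%), against 60, 52 and 62 reads in the other libraries. The most abundant feature took 5.47% in sufficient iron replicate 1, 4.09% in limited iron replicate 1 and 7.5% in limited iron replicate 2. Sequenced reads that held the internal adaptor made up 35.7% and 39.8% in sufficient iron, but 2.41% in limited iron replicate 1 and 27.1% in limited iron replicate 2. Across 6085 tested features, which are not independent replicates, log2 values of replicates correlated with r = 0.456 in sufficient iron and r = 0.459 in limited iron. Correlations between libraries of different groups ran from 0.400 to 0.494, so replicates were no closer to each other than to the other group.

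**Figure D1:**
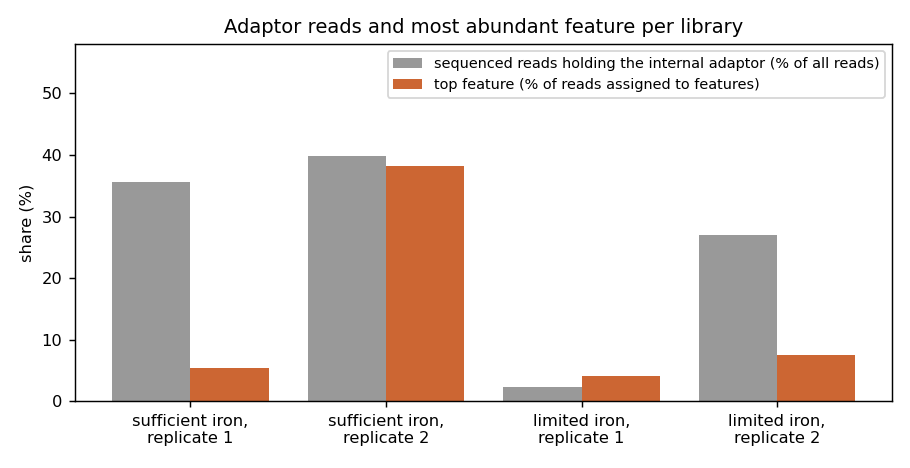
Share of sequenced reads that held the internal adaptor (grey bars) and share of assigned reads taken by the most abundant feature (orange bars), in percent, for each of the 4 libraries. Limited iron replicate 1 had 2.41% adaptor reads, and appA took 38.1% of the assigned reads of sufficient iron replicate 2.

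The first question was which genes differed in level when iron was limited. No feature passed the threshold, and the values of the genes with the smallest p are given here as values only. padR, whose name is that of a family of transcriptional repressors, was at 14.7 ± 0.0547 RPKM in sufficient and 333 ± 116 RPKM in limited iron (mean ± SD, n = 2 here and below), a relative log2 difference of 3.97 ± 1.03 (SE). The ribosomal protein genes rplF (14.5 ± 7.80 against 172 ± 14.7 RPKM) and rplE (15.5 ± 13.4 against 320 ± 264 RPKM) and the cortex hydrolase gene cwlJ, used when spores germinate (17.2 ± 19.1 against 198 ± 44.1 RPKM), were also higher in both limited iron libraries. In the other direction, cbiL, of the cobalamin pathway, was at 1839 and 229 RPKM in sufficient and at 39.8 and 25.5 RPKM in limited iron, a relative log2 difference of -4.70 ± 1.41.

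By limma, 0 of 6085 features passed an adjusted p of 0.05, and the smallest adjusted p was 0.98. An unadjusted p under 0.05 was reached by 268 features, where chance gives 304; 223 of the 268 were higher and 45 lower in limited iron, but 127 were higher and 100 lower of the 227 after median-of-ratios scaling. edgeR called 0 of 4696 features (310 at an unadjusted p under 0.05, where chance gives 235), and DESeq2 called 76, of which 28 were higher and 48 lower in limited iron. At an unadjusted p under 0.05 DESeq2 had 508 features, where chance gives 304. The other ways to split the libraries into pairs gave 266 and 393 features at that level by edgeR. Without limited iron replicate 1 limma called 34 features, without limited iron replicate 2 it called 12, and without either sufficient iron library in turn it called 0. Over all features the median log2 difference was 0.40, and 67.5% were higher in limited iron. After median-of-ratios scaling the median was -0.02 and 48.8% were higher. Without the 10 most abundant features, at equal totals, the median was 0.007 and 50.2% were higher. RPKM is scaled to the reads of the library, so the reads of appA lower every other RPKM value of sufficient iron replicate 2. After centring each library on its median, 1029 features were higher and 1023 lower in both limited iron libraries than in both sufficient iron libraries, 16.9% and 16.8% of those tested, where chance gives 16.7% each. RPKM values quoted for single genes are not centred. Before centring, yusV, fur on contig 386, ypeB, ptsG on contig 541 and sspF lay higher in both limited iron libraries, but after it they overlapped.

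The other symbols with the smallest raw p on the higher side were the thymidylate synthase gene thyA on contig 476 (44814 to 45529), celC, thiH on contig 504 (46660 to 48110), ytaF, cadR, mtnE on contig 236 (5389 to 6413), spoVT and metN on contig 534 (18683 to 19833). Their relative log2 differences ran from 1.96 for metN to 4.21 for cadR, with raw p from 0.0023 for thyA to 0.014 for metN; with 1 library left out, metN ranged from 1.24 to 2.74 and cadR from 2.02 to 6.32. Many rested on few reads: padR held 3, 5, 111 and 49 reads in sufficient iron 1 and 2 and limited iron 1 and 2, and cadR held 2, 0, 4 and 25. thiH was uneven within limited iron, at 669 and 106 RPKM, as was mtnE at 74.0 and 577 RPKM. Among features without a symbol, 32.0012 was at 9.79 ± 3.49 RPKM in sufficient and 1007 ± 803 RPKM in limited iron, and 556.0005 was at 185 ± 99.4 against 9.79 ± 2.58 RPKM.

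On the lower side, yvrD was at 1178 ± 383 RPKM in sufficient and 164 ± 43.3 RPKM in limited iron, a relative log2 difference of -3.22 ± 1.35. The pyrimidine synthesis gene pyrB was at 192 ± 61.8 against 40.7 ± 24.7 RPKM (-2.71 ± 1.12). The ATP synthase gene atpI (820 and 64.2 against 15.3 and 28.1 RPKM), mrnC (3725 and 411 against 236 and 134 RPKM), the anti-sigma factor gene flgM (212 ± 227 against 23.9 ± 12.6 RPKM) and xkdA on contig 264 (94.9 and 23.8 against 7.61 and 10.4 RPKM) were lower in both limited iron libraries but far apart within sufficient iron. The libraries of the groups overlapped before centring for vanR on contig 535 (3195 to 3655; 237, 33.3, 47.8 and 7.29 RPKM, relative log2 difference -2.57 ± 1.13) and ctaB (653, 78.0, 116 and 0 RPKM), and before and after it for ptsH on contig 541 (364, 29.6, 75.6 and 0 RPKM) and treR on contig 544 (33.0, 519, 50.2 and 11.5 RPKM). appA had a raw p of 0.0503 from sufficient iron replicate 2 alone. DESeq2 called padR (adjusted p = 0.015), rplE, thiH and mtnE as higher and cbiL (adjusted p = 0.00092), atpI, mrnC, yvrD and appA as lower in limited iron. Without independent filtering DESeq2 called 25 features, and of those just named only padR, cbiL and appA stayed called.

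The series is about sporulation under iron shortage, so spore genes were taken as the first group. Of 58 tested sporulation genes, 0 passed the test over all features or adjusted over the list alone; 9 were higher and 7 lower in both limited iron libraries after centring, and 42 overlapped. The list median lay 0.02 above that of all features (camera adjusted p = 0.92; adjusted p = 0.98 with an estimated correlation). Its centred medians were 0.08 and 0.44 in sufficient iron, 1.07 in limited iron replicate 1 and 0.26 in limited iron replicate 2, the first of which is the library with few adaptor reads. sigE, the gene of the early mother-cell sigma factor, was at 31.3 ± 11.2 RPKM in sufficient and 211 ± 55.6 RPKM in limited iron (relative log2 difference 2.34 ± 1.08, limma adjusted p = 0.98). spoIIAB, the gene of the anti-sigma factor that holds sigma F, was at 37.4 ± 4.21 against 247 ± 24.5 RPKM (2.29 ± 1.14), and spoVT, a forespore regulator, was at 21.6 ± 2.74 against 192 ± 119 RPKM (2.55 ± 1.00).

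Regulators of entry and most of the sigma factor genes overlapped between the groups, with sigE and the sigK feature on contig 545 as exceptions. The transcript of spo0A, the master regulator of sporulation, was at 56.1 and 184 RPKM in sufficient and at 374 and 40.3 RPKM in limited iron. abrB, a transition-state repressor, was at 72.7 and 728 against 315 and 245 RPKM. sigH was at 68.9 ± 22.2 against 83.6 ± 6.42 RPKM, and spo0J at 35.2 ± 34.7 against 61.2 ± 44.3 RPKM; these 4 were the measured genes of the initiation list, which was too small for a set test. The sigma factor genes sigF (338 and 349 against 1143 and 70.5 RPKM) and sigG (36.4 and 95.5 against 294 and 19.0 RPKM), with sigK on contig 470 (28.0 and 258 against 226 and 8.36 RPKM), were higher in limited iron replicate 1 than in limited iron replicate 2. The sigK feature on contig 545 (24088 to 24848) was at 37.5 ± 24.6 against 105 ± 5.57 RPKM.

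Mother-cell genes, forespore genes and germination genes were also taken apart, and 0 members of each passed over all features. Of 26 mother-cell genes, 3 were higher and 4 lower in both limited iron libraries, and the list's centred medians were 0.18 and 0.63 in sufficient iron and 1.32 and 0.30 in limited iron replicates 1 and 2 (camera adjusted p = 0.93). Their relative list median was 0.07 while camera's direction was down, and without limited iron replicate 1 the median was -0.55. spoIIM was at 297 and 48.7 RPKM in limited iron against 26.3 ± 22.8 RPKM, and spoIIIAB at 150 and 910 RPKM against 10.4 and 238 RPKM. Of 22 forespore genes, 4 were higher and 3 lower, with sspF, a small acid-soluble spore protein gene, at 22.9 and 198 against 314 and 1186 RPKM (camera adjusted p = 0.92). Of 19 germination genes, 3 were higher and 3 lower (camera adjusted p = 0.92). cwlJ alone passed adjusted over the list alone (adjusted p = 0.048, limma), with 5, 1, 49 and 26 reads; gerD was at 23.4 ± 15.1 against 80.0 ± 56.5 RPKM, ypeB at 19.1 ± 1.00 against 90.4 ± 92.1 RPKM and gerKC on contig 54 at 146 ± 151 against 32.5 ± 20.4 RPKM. The relative medians of the forespore and germination lists were -0.10 and -0.13 while their means and camera's direction lay above those of all features. Most members of both lists were the same gerKA, gerKB and gerKC features, so these lists are not separate readings.

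**Figure D2:**
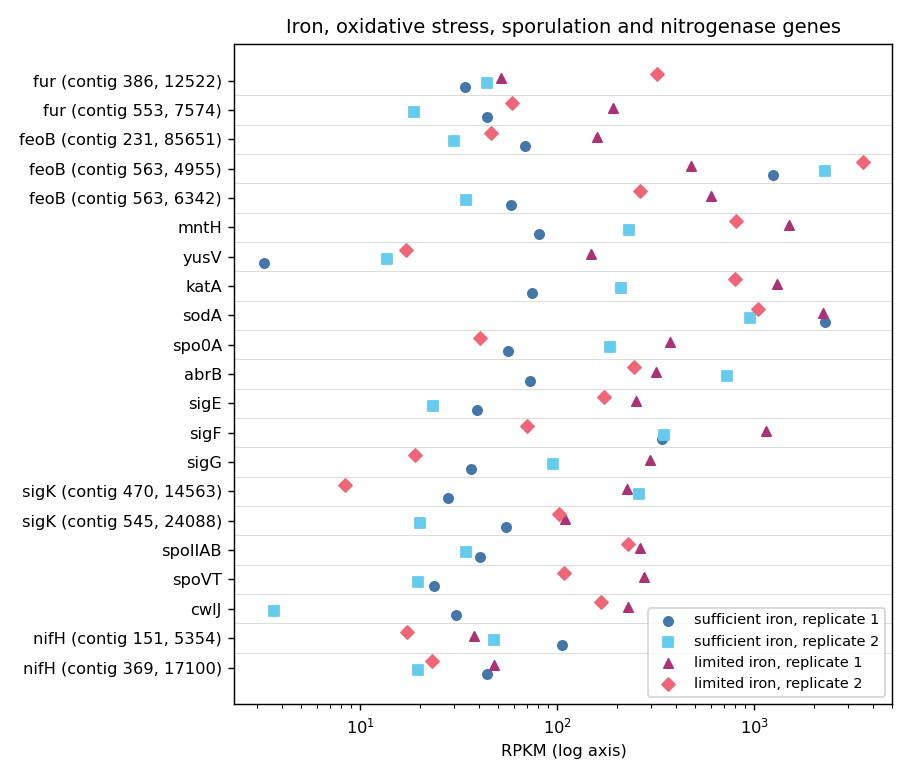
RPKM on a log axis of genes of iron handling, oxidative stress, sporulation and nitrogenase in each library; each point is 1 library, and features that share a symbol are told apart by contig and start. Of the 3 feoB features, that starting at 6342 on contig 563 lay higher in both limited iron libraries and the others overlapped. Levels of mntH, katA, sigE, spoIIAB, spoVT and cwlJ lay higher in both limited iron libraries, whereas sigF, sigG and spo0A were highest in limited iron replicate 1 and lowest in limited iron replicate 2; none of these differences passed the test.

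Iron uptake genes were the second group, as a direct readout of iron shortage. Of 27 tested members, 0 passed over all features or adjusted over the list alone; 6 were higher and 2 lower in both limited iron libraries, and 19 overlapped. The list median lay 0.08 above that of all features (camera adjusted p = 0.92; adjusted p = 0.98 with an estimated correlation). feoB on contig 563 (6342 to 7174), a ferrous iron permease gene, was at 46.2 ± 16.5 RPKM in sufficient and 431 ± 239 RPKM in limited iron (relative log2 difference 2.72 ± 1.27, limma adjusted p = 0.98). The other feoB features, chosen after their values were seen, overlapped between the groups: that on contig 563 from 4955 to 6429, which overlaps the first and held more reads, was at 1237 and 2269 against 476 and 3536 RPKM, and that on contig 231 (85651 to 87764) at 68.4 and 29.9 against 160 and 46.0 RPKM. The transcript of mntH, a manganese transporter gene, was at 156 ± 106 against 1148 ± 489 RPKM (2.60 ± 1.39). The siderophore transport gene yusV was at 3.26 and 13.6 against 149 and 17.0 RPKM. fur, which encodes the ferric uptake repressor in many bacteria, had a feature on contig 553 (31.4 ± 17.8 against 125 ± 93.6 RPKM) and another on contig 386 (33.9 and 43.9 against 51.7 and 319 RPKM).

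Enzymes that use iron came next, with 0 of 70 past the test. Of these, 15 were higher and 11 lower in both limited iron libraries (camera adjusted p = 0.92; adjusted p = 0.98 with an estimated correlation). porA was at 46.9 ± 4.68 against 462 ± 103 RPKM (relative log2 difference 2.86 ± 1.26) and was called by DESeq2 (adjusted p = 0.0496), but not without independent filtering. hemH on contig 244 (2002 to 3068), the ferrochelatase gene, was at 24.4 ± 16.7 against 144 ± 99.4 RPKM. The centred medians of the list were 0.32 and 0.64 in sufficient iron, 1.00 in limited iron replicate 1 and 0.34 in limited iron replicate 2.

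In genes that act against reactive oxygen and in chaperone or protease genes, both limited iron libraries had higher list medians than both sufficient iron libraries. Centred medians had the same order for ribosomal protein genes (1.22 and 1.53 in sufficient against 1.78 and 2.37 in limited iron). It also held narrowly for iron uptake genes (-0.066 and -0.049 against 0.128 and -0.025). Prophage and transposon genes had the reverse order (-0.095 and -0.339 against -0.340 and -0.474). The 8 oxidative stress genes had centred medians of 3.29 and 3.35 in sufficient and 4.44 and 4.36 in limited iron; 3 members were higher and 0 lower in both limited iron libraries, and 0 passed (camera adjusted p = 0.92). katA, a catalase gene, was at 142 ± 96.1 RPKM in sufficient and 1054 ± 357 RPKM in limited iron (2.63 ± 1.39, limma adjusted p = 0.98). trxB was at 367 ± 82.2 against 1073 ± 271 RPKM and msrA, with 4, 4, 8 and 5 reads, at 17.9 ± 6.38 against 31.6 ± 3.44 RPKM. trxA on contig 434 was at 772 and 2778 against 3861 and 1348 RPKM, and the superoxide dismutase gene sodA at 2290.4 and 945 against 2234 and 1042 RPKM. The list's median of relative differences was -0.02 while its mean lay above. Among 10000 random lists matched on mean level, the list was at percentiles 49.0 and 38.8 in limited iron replicates 1 and 2 against the other libraries.

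The 16 heat shock and protease genes had the highest relative list median, 0.98, with 7 higher and 0 lower in both limited iron libraries (camera adjusted p = 0.70; adjusted p = 0.98 with an estimated correlation). Without limited iron replicate 1 that median was 0.51 and without sufficient iron replicate 1 it was 0.45. Among random lists matched on mean level the list was at percentile 99.7 in limited iron replicate 1 and 35.7 in limited iron replicate 2. Random members were drawn independently, whereas the estimated correlation between members of this list was 0.15. clpP on contig 566 was at 10.7 ± 11.2 against 39.0 ± 0.0641 RPKM and on contig 422 (18302 to 18573) at 78.0 ± 9.74 against 295 ± 208 RPKM. The feature on contig 566 held 4, 1, 11 and 8 reads, too few for its small SD to show close replicates. ftsH, a membrane protease gene, was at 43.2 ± 16.9 against 156 ± 102 RPKM and lonA on contig 422 at 54.0 ± 28.3 against 156 ± 65.9 RPKM. trxA and trxB belong to both lists.

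**Figure D3:**
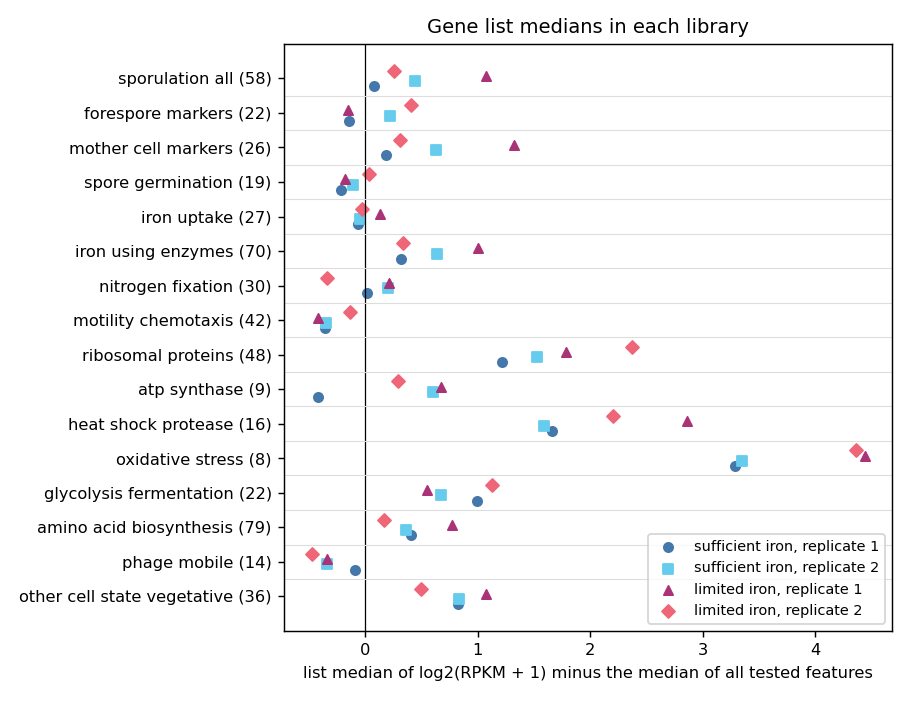
Median of log2(RPKM + 1) over the members of each gene list minus the median of all tested features, for each library; the number of tested members stands beside each list. Mother-cell genes stood at 1.32 in limited iron replicate 1 and between 0.18 and 0.63 in the other libraries, while oxidative stress genes stood at 4.44 and 4.36 in limited and 3.29 and 3.35 in sufficient iron.

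Genes of protein synthesis and metabolism gave 0 calls by limma, while DESeq2 called rplE among the ribosomal protein genes (adjusted p = 0.022) and atpI among the ATP synthase genes (adjusted p = 0.021). Neither was called by DESeq2 without independent filtering. Of 48 ribosomal protein genes, 11 were higher and 5 lower in both limited iron libraries (relative list median 0.27, camera adjusted p = 0.92); rpsK was at 27.1 ± 10.9 against 225 ± 204 RPKM and rplI at 52.0 ± 40.4 against 372 ± 115 RPKM. Of 9 ATP synthase genes, 2 were higher and 1 lower (0.43, camera adjusted p = 0.92); atpE was at 27.3 ± 10.9 against 88.0 ± 23.2 RPKM and atpG at 63.9 ± 51.0 against 166 ± 5.77 RPKM. Of 79 amino acid synthesis genes, 16 were higher and 6 lower (0.33, camera adjusted p = 0.70; adjusted p = 0.98 with an estimated correlation), and without limited iron replicate 1 the relative median fell to 0.09. leuC, of an iron-sulfur enzyme, was at 37.6 ± 5.50 against 148 ± 64.3 RPKM, while hisF was at 860 RPKM in limited iron replicate 1 and 23.4 RPKM in limited iron replicate 2. Of 22 glycolysis and fermentation genes, 1 was higher and 3 lower (camera adjusted p = 0.92); alsD was at 26.7 ± 1.21 against 68.0 ± 26.5 RPKM and ptsG on contig 541 at 47.3 ± 27.0 against 169 ± 63.4 RPKM. For this list and for that of dividing cells the median lay above all features while the mean and camera's direction lay below.

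Nitrogen fixation, motility, prophage and cell division genes did not pass either. Of 30 nitrogen fixation genes, 4 were higher and 6 lower in both limited iron libraries (relative list median -0.32, camera adjusted p = 0.92). nifH, the nitrogenase iron protein gene, was at 76.7 ± 41.4 against 27.6 ± 14.5 RPKM on contig 151 (5354 to 6324) and at 31.9 ± 17.2 against 35.3 ± 17.3 RPKM on contig 369 (17100 to 17974). nifD on contig 151 (6358 to 7925), next to that nifH, was at 24.1 ± 6.45 against 104 ± 71.5 RPKM, and the regulator gene glnR at 130 ± 110 against 44.8 ± 44.9 RPKM. Of 42 motility genes, 6 were higher and 7 lower (camera adjusted p = 0.92), with flgK at 31.5 ± 20.3 against 212 ± 168 RPKM and flgC at 14.5 ± 4.06 against 41.4 ± 1.89 RPKM (2, 5, 9 and 7 reads). Of 14 prophage and transposon genes, 2 were higher and 3 lower (-0.22, camera adjusted p = 0.92), with xkdN at 17.0 ± 2.74 against 40.6 ± 10.7 RPKM (3, 4, 10 and 5 reads). Of 36 genes of dividing cells, 6 were higher and 7 lower (camera adjusted p = 0.92), with ftsX at 18.8 ± 0.0702 against 65.8 ± 18.5 RPKM (6, 10, 22 and 24 reads) and murG at 27.5 ± 5.65 against 63.6 ± 20.2 RPKM. The list for secondary metabolites matched ppsA and fusA, of which fusA is the gene of a translation elongation factor, and was not tested as a set; ppsA was at 29.8 ± 2.75 against 68.0 ± 15.7 RPKM and fusA at 1017 ± 222 against 744 ± 144 RPKM.

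For no list was the camera adjusted p under 0.70, and by fry, which tests whether members move on balance in a common direction, the smallest adjusted p was 0.56. With 2 libraries in each group, an exact permutation test cannot give a two-sided p under 0.33. In simulated libraries with the spread of these, limma found 0 of 100 features changed 16-fold, so a difference of that size in a single gene was not detectable here by that test.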

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

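The tests of the DESeq2 calls against other groupings and simulated spread, the comparison of the limited iron libraries, the adaptor share and the copied read starts were chosen after the results were seen; the thinning and the share of reads held by 1 library were set before. Reads over conserved ribosomal RNA primer sites, counted in the read lists that the gene comparison does not use, were more frequent in both limited iron libraries than in both sufficient iron libraries at 3 of 6 sites. Over the fourth of 5 sites along the 16S gene there were 151 and 139 reads per 1000000 adaptor-free reads in limited iron replicates 1 and 2, against 32.5 and 54.0 in sufficient iron. At the fifth 16S site the values were 67.4 and 29.6 against 10.6 and 3.57, and at the 23S site they were 4268 and 311 against 108 and 196. The third 16S site ran the other way, with 68.4 and 47.9 in limited against 72.5 and 96.4 in sufficient iron, and the remaining 2 sites in 16S overlapped between the groups. Ribosomal RNA had been removed with a kit, so these reads are what was left after removal. An effect of iron cannot be told apart from uneven removal, and sites on the same RNA are not independent.

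DESeq2 called 76 features where limma and edgeR called 0. Of the 3 ways to split the 4 libraries into pairs, 2 gave at least 76 DESeq2 calls, the real split included, and the highest other split gave 121; 3 splits are too few for a share under 0.05. Features drawn unchanged, with the spread of these libraries, gave 78 false DESeq2 calls. That simulation also held 100 features changed 4-fold and 100 changed 16-fold, and calls among those loosen the adjusted threshold. False calls without any changed feature were not simulated, so 78 is not a count to set against 76. Spread between libraries stays a candidate source of false calls, of unknown number. In 94.7% of the called features a single library held most of the scaled reads, against 42.9% of other features with as many reads, but a large fold by itself gives such shares, so pile-ups in single libraries cannot be told apart from group differences by that value. An effect of iron on some of the 76 features stays open.

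Mother-cell genes stood high in limited iron replicate 1 and not in limited iron replicate 2, while forespore genes had centred medians of -0.16 and 0.41 and germination genes of -0.18 and 0.03 in those libraries. Most members of the forespore and germination lists are the same gerKA, gerKB and gerKC features, so their medians mainly describe those genes. The centred median of the 26 mother-cell genes exceeded the sufficient iron mean by 0.91 in limited iron replicate 1 (95% bootstrap interval over genes -0.01 to 1.80) and lay at -0.10 from it in limited iron replicate 2 (-0.96 to 0.65), which restates the pattern in single libraries for the list that showed it, so an effect of iron limitation stays open. Thinning could not decide whether a difference in total reads plays a part. It takes the same share from every feature, and rescaling and centring then restore the list median apart from sampling noise. With limited iron replicate 1 thinned to the assigned reads of replicate 2, its list median stayed 0.68 above the highest other library on average. The gap lay between 0.53 and 0.80 in 100 thinnings and at 0.69 before thinning. Depth per feature was not matched and stays open. The median feature held 25 reads in limited iron replicate 1 before thinning, against 15, 15 and 12 in the other libraries. Limited iron replicate 1 also had 2.41% adaptor reads, outside the range of the other libraries. Because the high list median and the low adaptor share fall in 1 library, library preparation and a difference between the cultures cannot be told apart. Genes are not independent replicates, so the intervals describe these libraries.

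Some features held nearly all their reads in a single library. The most abundant feature of limited iron replicate 2, which has no symbol, held 22362 reads there and 110, 175 and 42 in sufficient iron replicates 1 and 2 and limited iron replicate 1. Among read starts of 20 bases found almost only in that library, the one closest in count to the feature was taken. It had 22570, 60, 150 and 18 reads in those libraries, close in the first by that choice but more than 2-fold off in the last. The start was not placed on the feature, so a single copied fragment is possible but not shown. For appA, the largest adaptor-free read start found almost only in sufficient iron replicate 2 had 28230 reads against 198997 for the feature, which argues against a single copied start as its whole source. No biological explanation was tested for either feature.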

How the results depend on the processing

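The alternatives were fixed before the data were examined, except for DESeq2 without independent filtering and DESeq2 with other lengths, which were chosen after seeing the data; the causes of the changes below were not tested unless stated. The limma count of 0 features stayed 0 under every other pseudocount, filter, scaling and limma setting tried and by edgeR in 3 settings, with a smallest adjusted p from 0.47 to 0.97 in those limma settings. It moved to 76 by DESeq2, to 25 by DESeq2 without independent filtering and to 129 by DESeq2 with the 3n + 2 lengths of first features of a contig doubled too (16 features). With 1 library left out, it ranged from 0 to 34; the lone library of a group was then assumed to vary like the pair of the other. Deviations with the same replicate number correlated with r = -0.06 across features, which cannot show whether a number marks a shared preparation. Of adaptor reads, 35.4% and 41.8% began with the adaptor in replicate 1 of sufficient and limited iron. In replicate 2 of sufficient and limited iron these shares were 88.9% and 80.1%, so a preparation shared by number stays open. With the replicate number as a block, limma called 3 features. No list passed in any setting, and none with the block.

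Of 272 list values under alternatives, 253 kept their direction relative to all features. Limma without trend, robust limma, the replicate block and the other set tests leave these medians unchanged by construction, so their values could not reverse. Of the 64 values with 1 library left out 17 reversed, and of the 208 others 2 did. The oxidative stress median, -0.02, was 0.011 with a pseudocount of 5 and 0.23 without the 10 most abundant features. With 1 library left out, list medians ranged from -0.024 to 0.27 for sporulation, -0.13 to 0.15 for forespore, -0.55 to 0.34 for mother-cell, -0.18 to 0.15 for germination, -0.21 to 0.29 for iron uptake, -0.031 to 0.34 for iron-using, -0.35 to 0.011 for nitrogen fixation, -0.0017 to 0.59 for ribosomal, 0.057 to 0.26 for oxidative stress, -0.41 to 0.34 for glycolysis and -0.13 to 0.14 for dividing-cell genes. The lists that kept their direction ranged from 0.086 to 0.51 for amino acid synthesis, 0.45 to 1.20 for heat shock and protease, 0.38 to 0.71 for ATP synthase, 0.0022 to 0.092 for motility and -0.36 to -0.058 for prophage and transposon genes.

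Of 1580 values of 85 named features, 35 reversed their relative direction and 14 passed the threshold under an alternative. Limma without trend, robust limma and the replicate block leave these differences unchanged by construction, so their values could not reverse. With reads tested by edgeR, edgeR with DESeq2 size factors, edgeR without a filter and DESeq2, sigG (-0.04 by limma) was at 0.49, 0.47, 0.46 and 0.43, sigF (-0.67) at 0.19, 0.16, 0.16 and 0.14, and trxA on contig 434 (0.24) at -0.17, -0.17, -0.19 and -0.20. sigG was 0.033 with a pseudocount of 5 and 0.16 after quantile normalization; spo0A (-0.12) was 0.10 after quantile normalization and 0.011 by edgeR. With 1 library left out, values ranged from -1.71 to 1.68 for sigG, -2.39 to 1.11 for sigF, -1.05 to 1.46 for trxA, -1.44 to 1.25 for spo0A, -2.15 to 1.82 for abrB, -0.23 to 0.11 for sigH, -0.94 to 2.09 for spo0J, -3.34 to 0.77 for sigK on contig 470, -0.13 to 4.93 for spoIIIAB, -0.50 to 0.048 for nifH on contig 369, -0.21 to 2.89 for fur on contig 386, -2.43 to 0.95 and -0.10 to 1.18 for the feoB features from 4955 on contig 563 and on contig 231, -0.22 to 2.58 for adhB and -0.37 to 3.06 for xkdR. Among features with a relative log2 difference in the report that kept their direction, some had a log2 value that itself changed by a factor of more than 1.5. These ranged from 1.51 to 3.67 for katA, 1.48 to 3.65 for mntH, 2.02 to 6.32 for cadR, 1.24 to 2.74 for metN and -3.67 to -1.51 for vanR.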

Other observations

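The neighbour test below was set before its result was seen, except for its restriction to well-read features; the comparison of katA with mntH was chosen after their values were seen. Catalase and manganese transporter transcripts followed each other across the libraries. katA held 36, 171, 834 and 373 reads in sufficient iron replicates 1 and 2 and limited iron replicates 1 and 2, and mntH held 35, 168, 853 and 334. Scaled to its own total, each was within 1.10-fold of the other in every library. Among 688 features with at least 300 reads in all, neither had a closer match than the other, and 0.0216% of the 236328 pairs were as close, which is 51 pairs. Both were higher in the limited iron libraries, with relative log2 differences of 2.63 and 2.60 (1.51 to 3.67 and 1.48 to 3.65 with 1 library left out), and neither passed the test.

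Among 10000 random lists matched on mean level, the lists highest in limited iron replicate 1 against the other libraries were heat shock and protease genes (percentile 99.7), amino acid synthesis genes (percentile 99.3), iron-using enzymes (percentile 98.7), mother-cell genes (percentile 97.0) and all sporulation genes (percentile 96.8). In limited iron replicate 2 the same lists were, in that order, at percentiles 35.7, 14.8, 5.36, 0.11 and 8.3, and forespore genes were at percentile 86.6. Iron uptake genes were at percentiles 14.7 and 72.6 in limited iron replicates 1 and 2. Random members were drawn independently. In the lists named as highest, the estimated correlation between members ran from 0.15 for heat shock and protease genes to 0.31 for mother-cell genes. The percentiles are therefore more extreme than such members warrant. Most mother-cell genes also belong to the sporulation list, so these lists are not separate readings. These are descriptions of single libraries, over 12 lists and 4 libraries.

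Neighbouring genes of a bacterium often share a transcript, so a difference between the groups would be predicted to run across neighbours. Features without a symbol whose numbers follow each other on a contig were taken as neighbours, and their mean log2 levels correlated across 3359 pairs (r = 0.18, permutation p = 0.0001, the smallest these permutations can give), against r = -0.01 for features 20 apart. Their log2 differences between limited and sufficient iron correlated with r = 0.012 (permutation p = 0.49). With at least 50 reads on average in each feature the correlation was 0.14 over 142 pairs (permutation p = 0.097), so low depth may hide a shared difference and the test leaves the question open. The deviation of limited iron replicate 1 from the other libraries correlated between neighbours with r = 0.06 (permutation p = 0.0003), and that of the other libraries with r from -0.02 to 0.03. Genes are not independent, and 7 such correlations were computed.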
